A study of Mus musculus with 4 samples.

How the data were processed

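Poly(A) RNA of PyMT-A, a mammary tumour cell line from FVB/NJ mice named after the polyoma middle T oncogene, was sequenced in 4 libraries. Of these, 2 came from cells infected with an empty puromycin-resistance retrovirus (vector) and 2 from cells infected with the same kind of virus carrying Jagged1, a ligand of Notch receptors (Jagged1 cells). Per the labels' protocols, both lines were grown in DMEM with serum, RNA was taken up in Trizol, and messenger RNA was isolated on poly(A) beads before library construction. The deposited values are raw read counts per gene symbol, 1 column per library, not normalized and not pooled. Per the submitters' processing notes, the tools were STAR 2.6.0c and featureCounts 1.6.2, with the mm10 (GRCm38) mouse genome. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart. The counts also do not separate reads of the Jagged1 virus from reads of the cell's own Jag1 gene. The species of the Jagged1 cDNA in the virus is not given either, and reads of a cDNA from another species would align to mouse Jag1 only in part.

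The count table held 33677 gene symbols, of which 9024 were at 0 in all 4 libraries. In 27 names a gene symbol had been turned into a calendar date, and 2 names stood in the table repeatedly; these genes are not reported by name. Total counts were 15609720 and 12136227 for vector 1 and 2, and 20835208 and 13549258 for Jagged1 1 and 2. A count of 3, taken as the floor of detection, corresponded to 0.192, 0.247, 0.144 and 0.221 CPM in these libraries, a limit that covers counting error only. The 18S ribosomal RNA row Rn18s-rs5 took 0.982% of the counts of vector 1 (exact 95% binomial interval 0.977 to 0.987%), against 0.0735% in vector 2 (0.072 to 0.0751%), 0.177% in Jagged1 1 (0.176 to 0.179%) and 0.081% in Jagged1 2 (0.0795 to 0.0826%). Within each line the counts of the replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 32.3 for the vector pair and 50.6 for the Jagged1 pair, so each library was counted as 1 replicate. Nothing in the labels says that the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

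Samples were grouped by their titles, and 1 comparison was made, Jagged1 against vector, with 2 libraries in each group. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 13299 genes, and scaled with TMM factors. Each gene was tested with edgeR's quasi-likelihood F test (estimateDisp, then glmQLFit with robust = TRUE and legacy = TRUE) in R 4.3.3, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Positive log2 fold changes mean higher expression in Jagged1 cells, and standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled counts relative to library size (CPM), given as mean ± SD over the 2 libraries of a line. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so no such test was run.

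For groups of genes, 36 lists were fixed before the data were examined, from textbook knowledge of Notch signalling, chemokines, immune regulation, mammary cell types, metabolism, stress responses and markers of other cell types. Of these, 32 had at least 3 tested members and were tested with camera of limma 3.58.1 on the edgeR data, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. Every camera p in the text is of this kind unless an estimated correlation is named; under an estimated correlation 0 of the 32 lists passed. Members of a list were also adjusted over the list alone. The number of members with both Jagged1 libraries on the same side of both vector libraries is given for lists past the camera threshold. By chance this would be 16.7% in each direction, and over all tested genes 15.1% had both Jagged1 libraries lower and 13.9% had both higher. The count stands with the list where its share was highest, and the rest follow. Members below numbered 8 of 19 (myeloid chemokines), 7 of 20 (checkpoint) and 5 of 20 (NF-kB). They numbered 7 of 18 for NRF2, 6 of 21 for matrix proteases and 2 of 19 for p53 targets. Members above numbered 2 of 14 (mesenchymal), 4 of 17 (extracellular matrix) and 4 of 13 (mammary luminal). Medians within replicate numbers compare Jagged1 1 with vector 1 and Jagged1 2 with vector 2 in log2 CPM (prior count 2). The labels do not say that libraries of the same number were handled together. Running numbers in the sample descriptions alternate between vector and Jagged1 libraries, an order that would allow such pairs but does not state them.

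The rule for named genes was also fixed beforehand. It took Jag1, up to 10 genes in each direction past the threshold, the 4 members with the smallest p of each of 8 core lists on Notch and immune signalling, the 3 with the smallest p of each other list past the camera threshold, and the 2 most abundant markers of each other cell type. Genes named outside this rule were chosen after their values were seen. Gene positions come from the GENCODE M21 annotation on GRCm38, the build of the counts, matched by symbol; 11429 of the tested genes (85.9%) had a match.

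The test and list procedures were tested on simulated counts for Jagged1 against vector, with the real genes, means and library sizes, 13299 genes and 200 of them changed, in 10 runs. The changed genes were drawn only from those with a mean over 5 CPM. The gene test recovered 38.2% of the genes changed 2-fold, 94.9% of those changed 4-fold and 98.2% of those changed 16-fold. In that order these were 306, 759 and 393 correct calls. It also called 183 of 128292 unchanged genes (0.143%). Beside the correct calls, these 183 were a larger share of the calls than the adjusted threshold is meant to allow. A list of 20 genes lowered by 0.5 on the log2 scale was called in 10 of 10 runs, and 0 of 300 unchanged lists were called. The simulation drew each gene independently with spread of the same kind, and did not include differences shared by libraries of the same number. It could therefore not show how often the list test calls unchanged lists whose genes vary together. Nor could it show what share of changed genes the gene test recovers in the real libraries, where such differences are present.

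Alternatives fixed before the data were examined were other scalings (RLE factors, upper quartile, library size only), DESeq2 1.42.0, limma-voom, glmQLFit with legacy = FALSE or robust = FALSE, no low-count filter, a minimum mean of 5 CPM, a test for changes over 1.5-fold, the replicate number as a block, leaving out each library in turn, and leaving out Jag1. For the lists they were camera with an estimated correlation, fry, and a rank-based camera, and for the library similarity a prior count of 0.5. Leaving out Rn18s-rs5, and combining the block with an estimated correlation, were added after the data were seen. When 1 library of a line was left out, the remaining library was assumed to vary like those of the other line. Members of the lists that are missing from the count table (for example Hes5, Heyl and Ccl19) were not analysed here.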

Results

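The dataset compared the transcriptomes of PyMT-A mouse mammary tumour cells carrying an empty vector with those of the same cells transduced with Jagged1, in 2 RNA sequencing libraries per line. The series title names macrophage recruitment and the suppression of T cells in Jagged1 tumours, and the comparison asks which genes differ between the cultured tumour cells themselves. Total counts ranged from 12136227 in vector 2 to 20835208 in Jagged1 1, and between 19349 and 20707 genes had at least 1 count.

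The libraries did not separate mainly by line. The first principal component of log2 CPM held 51.6% of the variance and placed vector 1 (-31.1) and Jagged1 1 (-25.9) on one side and vector 2 (17.1) and Jagged1 2 (39.98) on the other. The second component, with 32.4%, separated the vector libraries (-27.1 and -15.1) from the Jagged1 libraries (34.5 and 7.72). Pearson correlations across genes were 0.980 within vector, 0.969 within Jagged1, 0.977 between the libraries numbered 1 and 0.982 between those numbered 2; genes are not independent replicates. The median log2 difference within each replicate number is therefore given beside the main results.

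**Figure D1:**
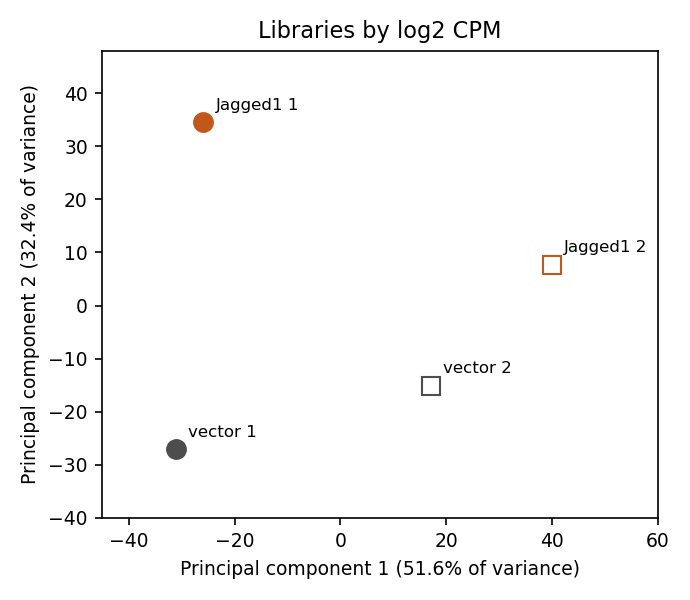
Scores of the 4 libraries on the first (51.6% of variance) and second (32.4%) principal components of log2 CPM, with vector in grey, Jagged1 in orange, circles for replicate 1 and squares for replicate 2. Replicate numbers part along the horizontal axis and the lines part along the vertical axis.

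Jag1, the transduced gene (chromosome 2, 137081456 to 137116644, minus strand, protein coding), was read 159 and 112 times in the vector libraries and 5676 and 4493 times in the Jagged1 libraries. Its level rose from 9.82 ± 0.984 CPM to 299.6 ± 35.2 CPM (SD, n = 2 per line), a 30.4-fold difference with a log2 fold change of 4.93 ± 0.20 (SE; adjusted p = 0.0111, edgeR). This is the difference in reads assigned to mouse Jag1; because the species of the transduced cDNA is not given, it need not equal the difference in total Jagged1 transcripts. Jag1 was the 1 gene of 13299 that passed the adjusted threshold, with 1 gene higher and 0 lower in Jagged1 cells. At an unadjusted p under 0.05 stood 526 genes (3.96%), against 665 expected by chance. This fit counted differences between the replicate numbers as spread, so the shortfall does not show that no other gene differed. A fit with the number as a block called more genes and is given with the processing alternatives. DESeq2 called 47 genes (19 higher, 28 lower) and limma-voom 1. Of the genes named below, DESeq2 called 16: Cxcl10, Cxcl11, Ifit3, Rsad2, Oasl1, Hspa5, Sdf2l1, Creld2, Chac1, Trib3, Ptgs2, Ccnd1, Fads1, Areg, Col5a1 and Flt1. Without the low-count filter 169 genes passed, among them these 16 other than Ccnd1, and Adam8, Adam12, Atf3, Ccl5, Cxcl2, Fosl1, Hey1, Mthfd2 and Notch3. Without vector 1 or vector 2 the adjusted p of Jag1 was 0.24 and 0.153 and 0 genes passed; without Jagged1 1 the count was 193 and without Jagged1 2 it was 49.

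**Figure D2:**
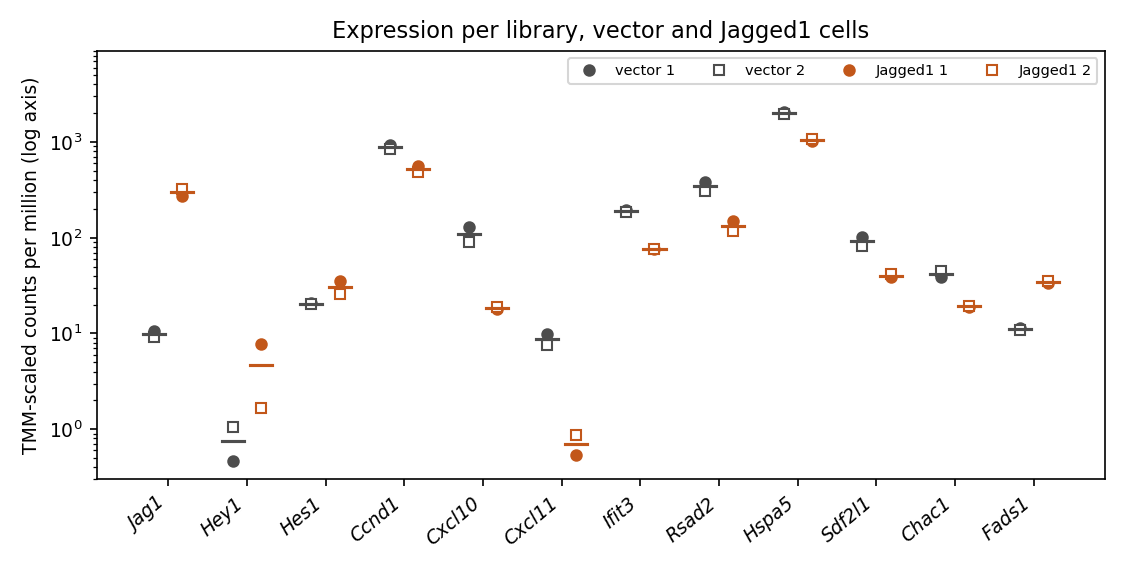
TMM-scaled CPM (log axis) of 12 genes in each library, with vector in grey and Jagged1 in orange, circles for replicate 1, squares for replicate 2 and bars for the mean of the 2 libraries of a line. Jag1 stood at 9.82 CPM in vector and 299.6 CPM in Jagged1 cells, and Cxcl10 at 111 and 18.6 CPM.

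Of the 32 gene lists tested, 16 passed the camera threshold, 4 higher and 12 lower in Jagged1 cells, and 0 passed with an estimated correlation. Splits of the libraries that do not follow the line also called lists, 12 for number 1 against 2 and 10 for the remaining split. Genes that Notch signalling switches on did not move together. Of 8 tested targets, 4 were higher and 4 lower in Jagged1 cells, and the list did not pass (adjusted p = 0.84); its median log2 fold change was -0.09, while its mean was 0.30 and the test pointed upward. The transcriptional repressor genes Hey1 (log2 fold change 2.65 ± 0.88) and Hes1 (0.59 ± 0.22) and the receptor gene Notch3 (0.84 ± 0.39) had higher values in Jagged1 cells, each with an adjusted p of 1. With 1 Jagged1 library left out these values moved: without Jagged1 1 they were 1.14, 0.33 and 1.22, and without Jagged1 2 they were 3.37 (adjusted p = 0.0335, a call), 0.80 and 0.33; Notch3 was also at 0.50 without vector 1 and 1.29 without vector 2. Without the low-count filter Hey1 and Notch3 passed over all genes (adjusted p = 0.000903 and 0.0261). Hey1 was low, at 0.761 ± 0.421 CPM in vector and 4.70 ± 4.30 CPM in Jagged1 cells. In 2 targets, Hey1 and Hes1, both Jagged1 libraries lay above both vector libraries, and in 2 targets both lay below. The lower targets were Nrarp (-0.364 ± 0.346), Cdkn1a (-0.362 ± 0.801), Myc (-0.299 ± 0.275) and Ccnd1. Ccnd1, which encodes cyclin D1, fell by 0.75 ± 0.17 on the log2 scale, the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0408; 0.914 over all genes). Among 22 receptors, ligands and processing factors the median was 0.07, with 12 higher and 10 lower and 0 passing either adjustment (adjusted p = 0.479, list test). Within it Notch1 was at 0.33 ± 0.20, the protease gene Adam10 at 0.36 ± 0.21 and the gamma-secretase gene Psen2 at -0.49 ± 0.27. Single libraries moved these: Notch1 was at 0.51 without Jagged1 1 and 0.12 without Jagged1 2, Adam10 at 0.15 and 0.54 in that order and at 0.56 and 0.20 without vector 1 or vector 2, and Psen2 at -0.31 without vector 2. The target list had medians of 0.31 without Jagged1 1 and 0.30 without vector 2, and the other Notch list stayed between 0.009 and 0.10.

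Chemokines that attract T cells were lower in Jagged1 cells. The list of 7 fell (median log2 fold change -1.52, adjusted p = 7.72e-17; adjusted p = 0.236 with an estimated correlation), and 4 members fell when adjusted over the list alone, against 0 over all genes. These were Cxcl10, from 111 ± 28.9 to 18.6 ± 0.648 CPM (log2 fold change -2.57 ± 0.23), Cxcl11 (-3.65 ± 0.42), Cxcl9 (-1.52 ± 0.36) and Ccl5 (-1.56 ± 0.31), with list-alone adjusted p-values of 0.000441, 0.000726, 0.0114 and 0.00666. Cxcl9, Cxcl10 and Cxcl11 encode ligands of the receptor CXCR3 and lie side by side on chromosome 5, at 92321347 to 92328079, 92346638 to 92348889 and 92359544 to 92365485, all on the minus strand; the annotation lists Cxcl11 as a polymorphic pseudogene of the reference strain. Over all genes the edgeR adjusted p was 0.419 for Cxcl10 and 0.46 for Cxcl11, against 3.82e-17 and 4.97e-07 with DESeq2. Both passed in edgeR without Jagged1 1 or Jagged1 2, and neither passed without vector 1 or vector 2. With 1 library left out Cxcl10 lay between -2.824 and -2.255 and Cxcl11 between -4.015 and -3.322. In 5 of 7 genes both Jagged1 libraries lay below both vector libraries, and the list median was -1.27 within number 1 and -1.31 within number 2. It was -0.95 without the low-count filter and -0.94 with a minimum mean of 5 CPM. Cxcl16 stood at -0.36 ± 0.18, Ccl27a at 0.74 ± 0.35 and Ccl25 at 0.08 ± 0.39.

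Interferon-stimulated genes, the antiviral and immune genes that interferons switch on, were lower in Jagged1 cells almost throughout the list. Of 30 tested members 28 had negative values, and in 25 both Jagged1 libraries lay below both vector libraries, where chance gives 16.7% for a single gene. Members of a list are not independent observations, so this count does not measure the strength of evidence. The list fell (median -0.36, adjusted p = 1.18e-24; adjusted p = 0.236 with an estimated correlation), with medians of -0.41 and -0.35 within numbers 1 and 2. Adjusted over the list alone, 8 members fell and 0 rose; over all genes 0 passed. Rsad2, the gene of the antiviral protein viperin, went from 348 ± 52.2 to 133 ± 22.1 CPM (-1.39 ± 0.20), Ifit3 from 191 ± 4.84 to 76.1 ± 0.706 CPM (-1.33 ± 0.14), Oasl1 from 215 ± 25.7 to 107 ± 5.06 CPM (-1.02 ± 0.16) and Ifit1 from 465 ± 2.15 to 293 ± 8.04 CPM (-0.67 ± 0.15). The others were Isg15, Mx1, Zbp1 and Dhx58. Rsad2, Ifit3 and Oasl1 passed over all genes without Jagged1 1, and Ifit3 also without Jagged1 2. None of them passed without vector 1 or vector 2. With 1 library left out Rsad2 lay between -1.573 and -1.205, Ifit3 between -1.363 and -1.282 and Oasl1 between -1.14 and -0.867. Ifit3 has a close copy, Ifit3b, so the division of reads between them is uncertain; Ifit3b stood at -1.02 ± 0.16.

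Genes for loading peptides on MHC class I molecules shared the direction with smaller values. All 17 tested members were lower, 9 of them with both Jagged1 libraries below both vector libraries, and the list fell (median -0.29, adjusted p = 1.1e-07; adjusted p = 0.484 with an estimated correlation). Psmb9, a subunit of the immunoproteasome, stood at -0.95 ± 0.28, the peptide transporter gene Tap1 at -0.53 ± 0.15, the chaperone gene Calr at -0.65 ± 0.16 and Pdia3 at -0.40 ± 0.16, while B2m was at -0.09 ± 0.18; 0 members passed when adjusted over the list alone. Psmb9 (chromosome 17, 34181987 to 34187764, minus strand) overlaps the start of Tap1 (34187553 to 34197225, plus strand), and reads in the overlap cannot be assigned without strand. The median was -0.47 within number 1 and -0.10 within number 2, and -0.15 without vector 1.

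Chaperones of the endoplasmic reticulum and genes of the ATF4 response were lower in Jagged1 cells. All 15 chaperone genes had negative values, 12 with both Jagged1 libraries below both vector libraries, and the list fell (median -0.60, adjusted p = 2.22e-24; adjusted p = 0.236 with an estimated correlation). Hspa5, the gene of the chaperone BiP, went from 2026 ± 63.2 to 1057 ± 28.0 CPM (-0.94 ± 0.15), Sdf2l1 from 91.9 ± 12.6 to 40.3 ± 1.80 CPM (-1.19 ± 0.17) and Creld2 from 107 ± 6.38 to 53.4 ± 0.930 CPM (-0.999 ± 0.15). These were among 8 members that fell when adjusted over the list alone, with 0 over all genes. The transcription factor gene Xbp1 was at -0.21 ± 0.22. The list of 22 ATF4 and amino acid stress genes had negative values in all members and also fell (median -0.57, adjusted p = 5.32e-22; adjusted p = 0.236 with an estimated correlation), in 15 of them with both Jagged1 libraries lower. Chac1, which degrades glutathione, stood at -1.12 ± 0.17, the pseudokinase gene Trib3 at -0.83 ± 0.15 and Mthfd2, of mitochondrial folate metabolism, at -0.80 ± 0.16; with Asns and Psph these were the 5 that fell when adjusted over the list alone. Sdf2l1, Creld2, Chac1 and Mthfd2 passed over all genes without Jagged1 1, and did not pass without Jagged1 2, vector 1 or vector 2. Medians within numbers 1 and 2 were -0.67 and -0.51 for the chaperones and -0.59 and -0.57 for the ATF4 list.

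**Figure D3:**
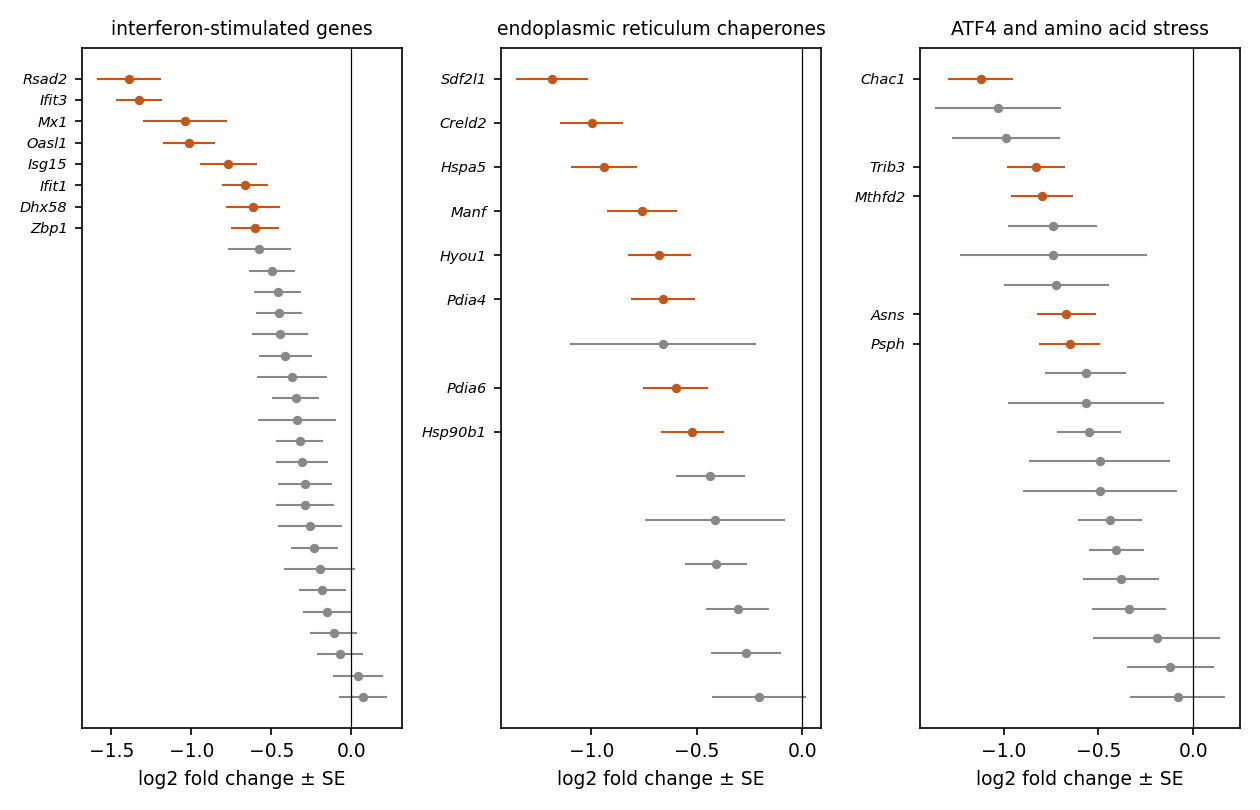
Log2 fold change (Jagged1 over vector) of each tested member of the interferon-stimulated, endoplasmic reticulum chaperone and ATF4 lists, with bars of 1 SE and orange, with gene names, for the 8, 8 and 5 members past the threshold when adjusted over the list alone; grey members are drawn without names. In these lists 28 of 30, 15 of 15 and 22 of 22 members have negative values.

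Chemokines and growth factors that act on macrophages and neutrophils were lower in the list test, and 1 library decided this. The list of 19 fell (median -0.37, adjusted p = 3.78e-06; adjusted p = 0.501 with an estimated correlation), with 4 members higher and 15 lower, and 0 past the threshold when adjusted over the list alone. Cxcl2 stood at -2.10 ± 0.48, the cytokine gene Lif at -0.56 ± 0.15 and Cxcl14 at 0.94 ± 0.28, beside Ccl5 as given above. Csf1, the macrophage growth factor, was at 474 ± 137 CPM in vector and 308 ± 118 CPM in Jagged1 cells (adjusted p = 1), and Ccl2, which attracts monocytes, stood at -0.78 ± 0.26 (adjusted p = 1). Without vector 1 Ccl2 was at -0.496, and without Jagged1 1 Cxcl14 was at 0.605. The median was -0.75 within number 1 and -0.14 within number 2. Without Jagged1 1, in which Cxcl5 was at 380 CPM and Il1a at 8.90 CPM against 2416 and 58.8 CPM in Jagged1 2, the list median was 0.11 (adjusted p = 0.426); it was -0.90 without Jagged1 2 and -0.16 without vector 2.

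Checkpoint ligands and immunosuppressive factors fell in the list test by a small amount (20 genes, median -0.13, adjusted p = 0.0397; adjusted p = 0.484 with an estimated correlation). Ptgs2, the gene of the prostaglandin enzyme COX-2, fell from 244 ± 10.98 to 134 ± 4.10 CPM (-0.86 ± 0.15), the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0293; 0.72 over all genes). Cd274, which encodes the checkpoint ligand PD-L1, was at 12.8 ± 0.0180 CPM in vector and 5.90 ± 1.30 CPM in Jagged1 cells (-1.11 ± 0.27, list-alone adjusted p = 0.0516), Pvr at -0.53 ± 0.14 and Tgfb3 at 0.64 ± 0.16. The list call was lost without vector 1 (adjusted p = 0.09), vector 2 (0.0835) or Jagged1 1 (0.709), and the median was -0.063 without vector 1, -0.22 without vector 2 and -0.33 without Jagged1 2. It was also lost with DESeq2 (adjusted p = 0.0621), rank-based camera (0.192), no low-count filter (0.0722) and a minimum mean of 5 CPM (0.0503), and the median was -0.37 within number 1, -0.06 within number 2 and -0.23 with limma-voom. NF-kB targets, 20 genes with 8 higher and 12 lower, had a median of -0.10 (adjusted p = 0.0397; adjusted p = 0.801 with an estimated correlation), and 0 members passed when adjusted over the list alone. The named members beside Cxcl2 and Ccl2 were Traf1, at -1.48 ± 0.58, and Ccl20, at -1.15 ± 0.63; Ccl20 was at -0.45 without Jagged1 1 and at -2.44 without Jagged1 2, where it passed over all genes (adjusted p = 0.0162). The NF-kB median was -0.39 within number 1 and 0.28 within number 2; the call was lost without vector 1 or vector 2 (adjusted p = 0.09 and 0.0835), with medians of -0.043 and -0.042. Without Jagged1 1 the NF-kB list was higher (0.10, adjusted p = 0.0271), and without Jagged1 2 its median was -0.47. The NF-kB call also ended with DESeq2 (adjusted p = 0.159), rank-based camera (0.327) and a minimum mean of 5 CPM (0.474, median -0.03), and the median was -0.06 without the low-count filter.

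Immediate early genes, which respond within minutes to growth factors and stress, were lower in Jagged1 cells in 17 of 18 members. The list fell (median -0.55, adjusted p = 7.96e-09; adjusted p = 0.432 with an estimated correlation), with 9 members lower in both Jagged1 libraries and 0 past the threshold when adjusted over the list alone. Atf3 stood at -1.03 ± 0.21, the AP-1 gene Fosl1 at -1.03 ± 0.25 and the phosphatase gene Dusp5 at -0.76 ± 0.22, while Fos was at -0.02 ± 0.21. Atf3, Fosl1 and Dusp5 passed over all genes without Jagged1 1, and did not pass without Jagged1 2, vector 1 or vector 2. Medians were -0.30 and -0.38 within numbers 1 and 2, and -0.19 without Jagged1 2. Targets of the oxidative stress factor NRF2 fell (18 genes, 15 lower, median -0.18, adjusted p = 0.00595; adjusted p = 0.484 with an estimated correlation), with Osgin1 at -0.70 ± 0.19, Slc7a11 at -0.72 ± 0.28 and Gsta4 at 0.37 ± 0.19. Slc7a11 was at -0.38 without Jagged1 1 and -1.15 without Jagged1 2, and Gsta4 at 0.18 without Jagged1 2. The NRF2 call was lost without vector 1 (adjusted p = 0.127) or Jagged1 2 (0.0623). The NRF2 median was -0.26 within number 1 and -0.12 within number 2, -0.28 without vector 2 and -0.062 without vector 1, and 0 NRF2 targets passed when adjusted over the list alone.

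The p53 target list and the matrix protease list passed with directions that depended on the libraries used. Of 19 p53 targets 13 were lower (median -0.16, adjusted p = 0.0385; adjusted p = 0.818 with an estimated correlation), with Plk2 at -0.59 ± 0.16, Aen at -0.42 ± 0.17 and Sesn2 at -0.57 ± 0.41; Sesn2 was at -0.11 without Jagged1 1, -1.21 without Jagged1 2 and -0.22 without vector 2. Within number 1 the median was -0.50 and within number 2 it was 0.04; without vector 2 it was 0.16 (adjusted p = 0.964), and without Jagged1 1 the list was higher (0.17, adjusted p = 0.0344). The p53 median was -0.39 without vector 1 and -0.78 without Jagged1 2, and the call ended with DESeq2 (adjusted p = 0.0621), rank-based camera (0.163) and a minimum mean of 5 CPM (0.0567). For the 21 matrix proteases and inhibitors the test pointed downward (adjusted p = 0.0271; adjusted p = 0.477 with an estimated correlation) while the median was -0.01 and the mean 0.05, with -0.25 within number 1 and 0.003 within number 2. Adam8 (-1.35 ± 0.28), Adam12 (-1.07 ± 0.29) and Plaur, the urokinase receptor gene (-0.71 ± 0.21), were its lowest by p. Adam12 and Plaur passed over all genes without Jagged1 1, and did not pass without Jagged1 2, vector 1 or vector 2. The protease call was lost with DESeq2 (adjusted p = 0.0621), rank-based camera (0.526) and without vector 2 (0.333) or Jagged1 1 (0.488), with medians of 0.14 without vector 1, 0.13 without vector 2, 0.18 without Jagged1 1 and -0.37 without Jagged1 2. Its median was -0.21 with limma-voom, -0.18 with a minimum mean of 5 CPM, 0.011 with DESeq2, 0.028 without the low-count filter, and between -0.005 and 0.016 under the other scalings. In both lists 0 members passed when adjusted over the list alone.

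The fatty acid synthesis list was higher in Jagged1 cells, with Fads1 moving most. The list of 16 rose (12 higher, 4 lower, median 0.21, adjusted p = 0.000138; adjusted p = 0.302 with an estimated correlation), and in 7 members both Jagged1 libraries lay above both vector libraries. Fads1, the delta-5 desaturase of polyunsaturated fatty acids, rose from 11.2 ± 0.361 to 34.4 ± 1.05 CPM (1.61 ± 0.17). It was the 1 member past the threshold when adjusted over the list alone (edgeR adjusted p = 0.00232, and 0.46 over all genes). Fads1 passed over all genes without Jagged1 1 or Jagged1 2, and did not pass without vector 1 or vector 2. With 1 library left out its value lay between 1.572 and 1.667. The delta-6 desaturase gene Fads2 stood at 0.56 ± 0.15 and the elongase gene Elovl6 at 0.49 ± 0.15. Fasn was at -0.146 ± 0.196, Acly at 0.068 ± 0.155 and Acaca at 0.147 ± 0.178, so the rise did not extend to every member. Medians were 0.05 and 0.21 within numbers 1 and 2, and the call was lost without vector 2 (adjusted p = 0.0564).

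Mesenchymal, extracellular matrix and mammary luminal genes also rose in the list test, and all 3 calls were lost without Jagged1 2. The mesenchymal list had a median of 0.62 (14 genes, 11 higher, adjusted p = 0.0373; adjusted p = 0.61 with an estimated correlation), the matrix list 0.11 (17 genes, 13 higher, adjusted p = 0.0351; adjusted p = 0.642 with an estimated correlation) and the luminal list 0.47 (13 genes, 11 higher, adjusted p = 0.0271; adjusted p = 0.642 with an estimated correlation). In each, 0 members passed when adjusted over the list alone. Medians within numbers 1 and 2 were 0.22 and 0.24 for the mesenchymal, 0.045 and 0.34 for the matrix and 0.35 and 0.51 for the luminal list. Without Jagged1 2 the medians were -0.03, -0.06 and -0.21 (adjusted p = 0.154, 0.568 and 0.718); without vector 1 the mesenchymal and luminal calls were also lost (adjusted p = 0.1 and 0.169), and without vector 2 or Jagged1 1 the mesenchymal median was 1.24 and 1.33 and the matrix median 0.40 and 0.49. The matrix median was 0.38 without vector 1, and the luminal median 0.81 without Jagged1 1. With limma-voom the mesenchymal (0.31, adjusted p = 0.146) and matrix (0.17, adjusted p = 0.14) calls ended, and with a minimum mean of 5 CPM all 3 did (adjusted p = 0.0838, 0.175 and 0.0503, with a mesenchymal median of 0.21). The matrix call also ended with rank-based camera (adjusted p = 0.114), and its median was 0.34 without the low-count filter. Vim, which encodes vimentin, was at 97.3 ± 2.89 CPM in vector and 216 ± 165 CPM in Jagged1 cells, with log2 differences of 1.80 within number 1 and 0.0024 within number 2, and it passed over all genes without Jagged1 2 (1.78, adjusted p = 0.00944), with 0.032 without Jagged1 1. Tnc stood at 0.63 ± 0.23, Twist1 at -0.29 ± 0.15, the luminal regulators Gata3 at 0.41 ± 0.14 and Elf5 at 0.60 ± 0.21, and the growth factor gene Areg at -1.06 ± 0.23. Tnc was at 0.38 without vector 1 and 0.96 without vector 2, and Elf5 at 0.38 without vector 2. Col1a1 was counted 16, 24, 36 and 376 times in vector 1, vector 2, Jagged1 1 and Jagged1 2, and Col5a1 averaged 0.0407 ± 0.0576 CPM in vector and 5.51 ± 6.50 CPM in Jagged1 cells. Col1a1, Col5a1 and Areg passed over all genes without Jagged1 1, and did not pass without Jagged1 2, vector 1 or vector 2. Without Jagged1 2 the log2 fold change was 0.22 for Col1a1 (3.26 with all libraries) and 4.38 for Col5a1 (6.93). Jagged1 2 also held the fibroblast transcripts Col1a2 (280 counts) and Col3a1 (83 counts), both at 0 in the other 3 libraries, and 103 counts of Pdgfrb against 9 in Jagged1 1 and 0 in vector.

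**Figure D4:**
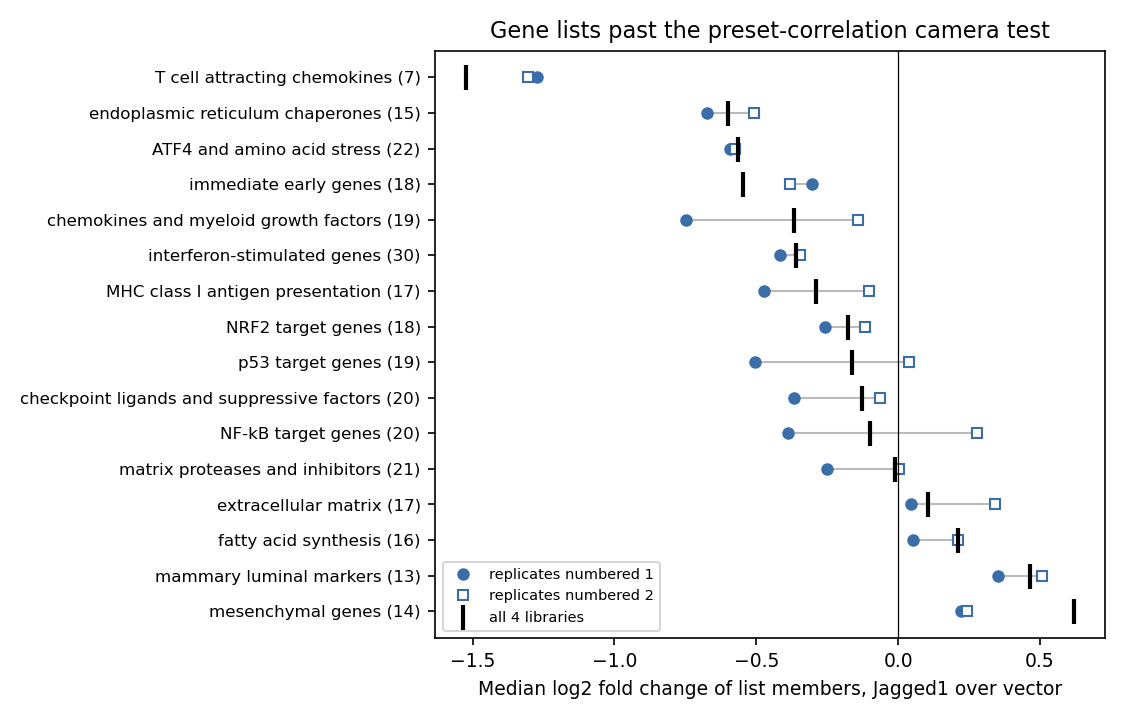
Median log2 fold change (Jagged1 over vector) of the 16 lists past the camera threshold with preset correlation, with tested members in brackets, black bars for all 4 libraries, circles for replicates numbered 1 and squares for replicates numbered 2. The T cell chemokines lie lowest at -1.52 and the mesenchymal genes highest at 0.62, and the NF-kB (-0.39 and 0.28), p53 (-0.50 and 0.04) and matrix protease (-0.25 and 0.003) lists change sign between the numbers.

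The other 14 lists beside the Notch lists did not pass. Cell cycle genes gave medians of 0.06 for mitosis (24 genes, adjusted p = 0.178) and -0.10 for DNA replication (26 genes, adjusted p = 0.334), and 1 library left out gave calls in both directions. Mitosis was at 0.21 without vector 1 (adjusted p = 0.00479), -0.21 without Jagged1 1 (0.0228) and 0.30 without Jagged1 2 (2.2e-07), and DNA replication at -0.24 without vector 2 (0.00265), -0.48 without Jagged1 1 (9.55e-09) and 0.21 without Jagged1 2 (0.000151). Epithelial genes were at -0.08 (24 genes, adjusted p = 0.216) and basal and myoepithelial markers at -0.015 with a mean of 0.28 (13 genes, adjusted p = 0.339). The first passed without Jagged1 2 (-0.14, adjusted p = 0.0326) and the second without vector 1 (0.37, adjusted p = 0.04). Hypoxia and glycolysis stood at 0.09 (adjusted p = 0.339), nuclear oxidative phosphorylation genes at -0.04 (adjusted p = 0.51), mitochondrially encoded mRNAs at 0.13 (adjusted p = 0.178), ribosomal proteins at -0.04 (adjusted p = 0.492) and cholesterol synthesis at 0.01, with the test pointing downward (adjusted p = 0.982). Without vector 1 hypoxia passed (0.34, adjusted p = 0.000275), as it did without Jagged1 1 (0.235, adjusted p = 0.00479). Without vector 2, mitochondrially encoded mRNAs (0.56), oxidative phosphorylation (-0.18) and ribosomal proteins (-0.15) passed (adjusted p = 0.000116, 0.0093 and 0.0237), and the first 2 also without Jagged1 1 (0.302 and -0.151, adjusted p = 0.0442 and 0.0344).

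Target lists of signalling pathways were at -0.11 for YAP and TEAD, with a mean of 0.11 (adjusted p = 0.339), 0.10 for TGF-beta (adjusted p = 0.365), 0.26 for BMP (adjusted p = 0.216) and 0.09 for Wnt (adjusted p = 0.302). BMP targets passed without vector 1 (0.47, adjusted p = 0.0312) and Jagged1 2 (0.51, adjusted p = 3.03e-05), and were at 0.12 without vector 2 and -0.31 without Jagged1 1 (adjusted p = 0.989). With 1 library left out TGF-beta targets ran from 0.030 to 0.24 and Wnt targets from 0.064 to 0.40, and YAP and TEAD targets passed with a minimum mean of 5 CPM (-0.12, adjusted p = 0.0177). When adjusted over the list alone, 0 members of these and the preceding lists passed, except 2 YAP and TEAD targets, Ankrd1 (-0.94 ± 0.17) and Rbms3 (3.76 ± 0.61).

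Markers of other cell types were mostly near the floor. The 4 tested macrophage and myeloid markers had a median of 0.43 (adjusted p = 0.546), which was 1.197 without Jagged1 1, where the list passed (adjusted p = 0.00759), and -1.89 without Jagged1 2; it was 0.17 without vector 1 and 2.003 without vector 2. Among other markers the pan-leukocyte gene Ptprc had 1, 1, 0 and 1 counts in vector 1, vector 2, Jagged1 1 and Jagged1 2. Lyz2 was read 0 and 71 times in vector and 0 and 89 times in Jagged1 cells, and Aif1 8 and 12 times in vector and 13 and 52 times in Jagged1 cells. T and NK cell markers other than Lck (34, 20, 25 and 15 counts) were at 3 counts or fewer. Of the endothelial markers, Flt1, a VEGF receptor gene, was at 1.43 ± 0.0548 CPM in vector and 5.93 ± 0.0977 CPM in Jagged1 cells (log2 fold change 2.05 ± 0.35; adjusted p = 0.72 over all genes, 0.00284 when adjusted over the list alone, where it rose), and Cdh5 had 6 and 32 counts in vector and 10 and 84 in Jagged1 cells. Pdgfra, a fibroblast marker, was at 0.83 ± 0.34, with 51 and 61 counts in vector and 166 and 93 in Jagged1 cells. Adipocyte markers reached at most 16 counts (Lpl in vector 2). The T and NK, fibroblast, endothelial and adipocyte lists had fewer than 3 tested members and were not tested as lists.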

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

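The alternatives that left out Rn18s-rs5 or joined the block to an estimated correlation were chosen after seeing the data; the others were planned. The count of changed genes stayed at 1 under RLE, upper quartile and library size scaling, limma-voom, legacy = FALSE, robust = FALSE, a minimum mean of 5 CPM, a 1.5-fold threshold and without Rn18s-rs5. It was 47 with DESeq2, 169 without the low-count filter and 0 without Jag1, and between 0 and 193 with 1 library left out; the cause was not tested, except that leaving out Jag1 removes the 1 call. The log2 fold change of Jag1 lay between 4.804 and 5.057 with 1 library left out, and it lost its call without vector 1 or vector 2. The 16 lists past the threshold became 0 with an estimated correlation and 0 with fry, both of which use the spread between these 4 libraries. The count was 11 with rank-based camera, 12 with DESeq2, 14 with limma-voom and 11 with the 5 CPM minimum; with 1 library left out the count was 16 to 20. Neither legacy, robust nor the fold threshold enters camera. Of the named genes other than Jag1, 1000 values under the alternatives kept direction and side of the threshold, 72 became calls (24 of them without the filter, 18 without Jagged1 1, 16 with DESeq2, 7 without Jagged1 2 and 7 under the block) and 5 reversed; of the lists, 447 kept, 78 lost the call, 17 gained it and 33 reversed. The first component held 50.9% of variance with a prior count of 0.5.

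With the replicate number as a block, 1234 genes stood at an unadjusted p under 0.05 and 17 passed the adjusted threshold (7 higher, 10 lower). Of these 17, DESeq2 also called 15, and 7 were among the named genes beside Jag1 (Cxcl10, Cxcl11, Ifit3, Rsad2, Fads1, Hspa5 and Col5a1). Under the block 16 lists passed, which became 0 with an estimated correlation as well. Deviations of same-numbered libraries from their line's mean correlated at 0.425 across genes; with 2 pairs and no statement in the labels, a shared day or batch stays open as a possible explanation.

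Directions of tests that were not past the threshold turned in these cases, and the cause was not tested. Cholesterol synthesis turned upward with library size only (median 0.035), upper quartile (0.013), DESeq2 (0.013), limma-voom (0.010) and the 5 CPM minimum (0.027). Lyz2 was at -0.38 with limma-voom. Notch targets turned downward without the filter (-0.25) and with the 5 CPM minimum (-0.31), and macrophage markers without the filter (median 0.12).

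Leaving out 1 library turned the test of further results, for which fewer samples is the construction; the lowest and highest values follow. Among genes they were -8.51 and 8.71 for Lyz2, -0.24 and 2.33 for Aif1 and -1.59 and 2.99 for Cdh5. Among lists not past the threshold the medians ran from -0.064 to 0.31 for Notch targets, 0.009 to 0.10 for Notch receptors, 0.039 to 0.37 for basal markers, -0.21 to 0.30 for mitosis, -0.48 to 0.21 for DNA replication, -0.027 to 0.34 for hypoxia, -0.11 to 0.094 for cholesterol synthesis, -0.12 to -0.003 for YAP and TEAD targets, -0.14 to 0.56 for mitochondrially encoded mRNAs, -0.18 to 0.12 for oxidative phosphorylation, -0.15 to 0.10 for ribosomal proteins and -1.89 to 2.003 for macrophage markers. Among lists past it they ran from -0.90 to 0.11 for myeloid chemokines, -0.33 to -0.063 for checkpoint ligands, -0.47 to 0.10 for NF-kB targets, -0.21 to 0.81 for luminal markers, -0.37 to 0.18 for matrix proteases and -0.78 to 0.17 for p53 targets. The T cell chemokine, MHC class I, interferon-stimulated, ATF4, chaperone and immediate early lists kept direction and call in each of the 4 fits. Genes near 3 counts, such as most markers of other cell types, could not be compared at this depth.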

Other observations

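All tests of explanations given here were chosen after the results were seen. Several genes outside the fixed lists, chosen after their values were seen, differed in mean between the lines; each was among the 47 genes called by DESeq2, and each had an edgeR adjusted p between 0.46 and 0.914. The secreted signalling gene Wnt7a was at 22.9 ± 0.0985 CPM in vector and 6.64 ± 0.624 CPM in Jagged1 cells (log2 fold change -1.79 ± 0.20, SE), the endothelial lipase gene Lipg at 123 ± 8.80 and 54.3 ± 4.19 CPM (-1.18 ± 0.16), the stress kinase gene Plk3 at 79.3 ± 6.52 and 34.3 ± 1.68 CPM (-1.21 ± 0.16) and the chromatin factor gene Hmga2 at 166 ± 4.16 and 87.8 ± 6.14 CPM (-0.92 ± 0.15). Cmpk2 (-0.99 ± 0.18) and Gbp4 (-0.98 ± 0.15), which interferons are known to induce, and Slfn3 (-3.17 ± 0.48) were lower in Jagged1 cells, like the interferon-stimulated list. Tigit, known as a checkpoint receptor of T cells, was at 31.2 ± 0.892 CPM in vector and 10.1 ± 4.66 CPM in Jagged1 cells (-1.64 ± 0.34), in libraries where Cd3e and Cd3g had 0 counts. On the other side stood Peg3 (1.59 ± 0.39), an imprinted gene, Aldh3a1 (1.44 ± 0.30), an aldehyde dehydrogenase, and Il1rl1, the interleukin 33 receptor gene, at 0.328 ± 0.00341 CPM in vector and 3.83 ± 2.14 CPM in Jagged1 cells.

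The libraries numbered 2 differed from those numbered 1 in many lists, markers of other cell types among them. With the line in the edgeR model, 13 genes passed for this difference, 10 higher and 3 lower in number 2, and 13 lists passed in camera, 8 higher and 5 lower. Trp53inp1, a p53 target, was at 30.5 and 128 CPM in vector 1 and 2 and at 35.1 and 179 CPM in Jagged1 1 and 2, and Ccng1 at 176, 359, 158 and 383 CPM in that order. The p53 list had a median log2 difference of 0.91 (adjusted p = 4.91e-21), DNA replication -0.55 (adjusted p = 1.05e-15) and mitosis -0.40 (adjusted p = 3e-07). Larger medians than that of the p53 list belonged to the 4 tested macrophage and myeloid markers (2.002, adjusted p = 4.34e-06), with Lyz2 at 0 counts in both libraries numbered 1, and to mesenchymal genes (0.93, adjusted p = 0.00148). Luminal markers (0.64), mitochondrially encoded mRNAs (0.55, and 0.14 after a fit on GC content and length), NF-kB targets (0.28), myeloid chemokines (0.25) and ATF4 genes (0.18) were also higher, and BMP targets (-0.425), oxidative phosphorylation (-0.24) and ribosomal proteins (-0.155) lower. Values with an estimated correlation were not computed. The basal keratin gene Krt14 was lower in number 2 of both lines (453 and 225 CPM in vector, 741 and 357 CPM in Jagged1 cells), as was Id4 (24.1, 5.4, 21.1 and 2.7 CPM).

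The interferon-stimulated, chaperone and ATF4 genes were lower in Jagged1 cells in nearly all members, as were the MHC class I (17 of 17) and immediate early (17 of 18) genes. Explanations were examined for the interferon-stimulated, chaperone and ATF4 lists. A trend with GC content and gene length as the whole cause is argued against by the medians after such a fit, -0.37 for the interferon-stimulated list (-0.36 before, 95% bootstrap interval -0.49 to -0.27) and -0.57 for the chaperones (-0.60 before, -0.72 to -0.41). Leukocytes in the vector cultures stay open, since the 28 macrophage, myeloid, T and NK markers in the table, most of them near the floor, summed to a mean of 10.1 CPM before scaling in vector (5.51 and 14.7) against 10.9 in Jagged1 cells (4.42 and 17.4), with Lck lower and Csf1r higher in both Jagged1 libraries. Splits of the 4 libraries number 3, too few for a share under 0.05. The real split called 16 lists and the others 12 and 10, so chance stays open. The smallest adjusted p of camera with preset correlation was 1.18e-24 for the real split. It was 9.03e-18 for number 1 against 2 and 6.52e-13 for the remaining split. Very small p-values of this test therefore also arose in splits that do not follow the line. With 1 line of each kind, an effect of Jagged1 and any other difference between the lines are confounded by the design, and neither was tested.

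The split of the libraries by number on the first component may reflect a shared culture day, culture density or library batch, none of which the labels give; a correlation that bears on this is given with the replicate block. Depth as the cause is argued against by the 51.2% of variance that the first component held after all libraries were thinned to the same depth (51.6% before). A trend with GC content and gene length is argued against for the p53 list, with a median of 0.93 after the fit (0.91 before). Carry-over of ribosomal RNA in vector 1 alone is argued against by a larger p53 shift between the Jagged1 libraries (1.23) than between the vector libraries (0.58). The 18S share was higher in number 1 than in number 2 of both lines. It was 0.982 against 0.0735% in vector and 0.177 against 0.081% in Jagged1 cells, so a difference of this kind between the numbers stays open. No biological explanation of this split was tested, since the number is not a group of the design.

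Fibroblast genes in Jagged1 2 formed a set: 7 of the 11 fibroblast markers in the table had at least 10 counts there and at least 5 times the rate of every other library, which is what fibroblasts or fibroblast-like cells in that culture might give. Against a full fibroblast profile stood Lum and Thy1, both at 0 counts in that library. The mesenchymal list was also higher in vector 2 than in vector 1 (median 0.74), and a part played by a batch shared by the libraries numbered 2 was not tested. A mesenchymal change in part of the tumour cells cannot be told apart from admixture, because a small share of such cells would leave the epithelial list near its observed median difference of -0.016 from vector 2. Grem1, a fibroblast-expressed BMP antagonist, was at 2.03 and 13.5 CPM in Jagged1 1 and 2 and at 0 in vector, so the signal was not wholly confined to Jagged1 2.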
